A study of Mus musculus with 2 samples.

How the data were processed

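Open chromatin was mapped by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in midbrain tissue pooled from mouse embryos at embryonic day 16.5. The labels describe 2 biological replicates of mixed sex from strain B6NCrl, each a pool of tissue. They form 1 group, so no comparison between conditions was possible. For replicate 2 the labels give a pool of 37 embryos. For replicate 1 the pool size was not given in the sources used here.

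The authors deposited peak lists, per the file headers and the texts that accompany them, on assembly mm10, the same assembly as GRCm38. The aligner, the peak caller and their versions were not given in the sources used here, nor was any shift of reads for the transposase offset. Per the accompanying texts, peaks were called for each replicate on its own alignments and for the pooled reads of both. Each peak carries a signal value that the authors deposited, read here as fold enrichment (a ratio), and a deposited −log10 p and −log10 q. The fold enrichment is the authors' own value for each peak and was used to describe and rank peaks within a list and, for 1 set of promoters, to compare their median with that of CpG-matched genes within a list. The ranked lists also hold, as deposited, the −log10 of the irreproducible discovery rate (IDR), which measures how well peak ranks repeat between 2 read sets, and the −log10 p of each peak in both sets. The thresholded lists hold peaks with an IDR of at most 0.05, but a few such peaks are left out of them. Per the accompanying texts these lists derive from 1 more file than the ranked lists do, and the content of that file was not given in the sources used here.

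The conservative list, which holds pooled peaks that pass the IDR threshold between the true replicates, was the main set. For each replicate its own IDR thresholded list was used, made by the authors from random splits of its reads (pseudoreplicates). A looser list, thresholded by overlap between replicates in place of IDR, served as an alternative. The deposited lists held several summits per accessible region, so overlapping entries were merged into regions, each with the highest fold enrichment and the summit of its strongest peak. Read totals are not part of these lists, so the sequencing depth of each replicate is unknown and precision is given by the spread of the 2 replicates. Intervals on shares are 95% Wilson intervals and cover counting error only.

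Genes and transcript starts came from GENCODE release M21 and sequence from the GRCm38.p6 assembly. A promoter region lay within 1000 bp of the start of a protein-coding transcript, other regions were called distal, and each distal region on chromosomes 1 to 19 and X was assigned to the nearest protein-coding start. The 18 gene lists, the 22 consensus strings, the tests and the rule for named genes were fixed before the data were examined. By that rule the text names, per list, the 3 members with the highest promoter fold enrichment and the first 3 in alphabetical order with no promoter region in either replicate's list. It also names the first 10 list members with a promoter region in 1 replicate only, the 10 genes with most distal regions, the 10 with the highest promoter fold enrichment and the 5 distal regions with the highest fold enrichment. Some members that this rule takes are given as counts, and genes near a distal region are named by the nearest start. Of 373 list genes 372 were matched, and Ahsp of the erythroid list was not in the annotation.

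Replicates were compared by overlap of at least 1 bp, with chance levels from 100 circular shifts of the regions along each chromosome. Promoter calls of each list were compared with those of all other protein-coding genes by a two-sided Fisher's exact test. Distal regions per gene were compared with 10000 random lists matched in 10 bins on the distance between the neighbouring genes' starts, in a two-sided permutation test. That distance used the most upstream start of each gene, whereas regions were assigned to the nearest of all starts. The bin of the longest territories has no upper limit. Consensus matches within 100 bp of distal summits were compared with windows centred 1000 bp to either side. Ratios have intervals from 1000 bootstrap draws of regions, and an exact two-sided binomial test used the regions where only the summit or only the upstream flank matched. P-values were adjusted by the Benjamini-Hochberg method over the lists or the consensus strings. Genes and regions are not independent replicates, so these p-values describe the lists within these libraries and not the spread between animals.

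Alternatives covered each replicate on its own, looser and stricter peak sets, promoter windows of 500 and 2000 bp, 1 start per gene, a background matched in 10 bins on the CpG content within 500 bp of the start, other assignments of distal regions, 50% reciprocal overlap, shuffled consensus strings and a 50 bp window. CpG and GC content were counted at the most upstream start of each gene, whereas a promoter region at any of its starts counted. The matching therefore does not always describe the promoter that was scored. Flanks at 5000 bp and a correlation over merged regions were added after seeing the data. Tests were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and sequences were matched with blastn 2.17.0. On simulated data for the 21646 genes, the list test on promoters recovered 80 of 80 changed lists with 1 call among 280 unchanged ones. The permutation test on distal regions recovered 15 of 15 with 1 call among 75. The planted changes were large, so these counts do not show how often smaller changes would be found.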

Results

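Accessible chromatin was profiled by ATAC-seq in midbrain tissue of mouse embryos at embryonic day 16.5, in 2 biological replicates of 1 group. Replicate 1 had 62804 IDR thresholded peaks, which merged into 20933 regions, and replicate 2 had 48735 peaks in 17150 regions (mean 19041.5 ± 2674.98 regions, SD, n = 2). The conservative set, supported by both replicates, held 76528 peaks in 25167 regions with a median width of 1103 bp, covering 27.5 Mb or 1.01% of the genome. Its peaks were called on the pooled reads, and it is larger than either replicate's own list. Read totals are not in the lists, so depth is unknown. Values are given for the conservative set unless a replicate is named, and all positions are on GRCm38/mm10. The design holds a single tissue and age, so the comparisons lie between replicates, genomic classes, gene groups and sequence motifs.

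Most accessible regions were found in both replicates. Of the regions of replicate 1, 74.7% (95% Wilson interval 74.1% to 75.3%) overlapped a region of replicate 2, and 91.8% (91.3% to 92.2%) of the regions of replicate 2 overlapped a region of replicate 1. Circularly shifted regions gave 1.38% and 1.68%. With both lists reduced to the 17150 regions of highest fold enrichment the shares were 82.0% and 83.0%. Promoter regions were found for 12013 protein-coding genes in replicate 1 and for 11433 in replicate 2, of which 11241 were in both. Across 146813 ranked peaks, the −log10 p of the replicates had a Spearman's rho of 0.695. Between random splits of 1 replicate's reads rho was 0.681 over 122663 ranked peaks for replicate 1 and 0.670 over 97932 for replicate 2. Each split holds only part of 1 replicate's reads, and the peaks ranked differ. These values therefore do not show whether replicates repeat each other better or worse than splits do. Among the ranked peaks in the conservative list, rho between the replicates was 0.749. Over merged regions of the replicates' lists that shared at least 1 bp, a comparison added after seeing the data, rho was 0.939. That value takes the highest −log10 p of each region in thresholded lists, so it is not comparable with those over single peaks. Peaks are not independent replicates, so no p-value is attached.

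Accessible regions were concentrated at gene starts. Promoters held 49.4% of the regions, gene bodies outside promoters 22.0% and intergenic DNA 28.6%. Shifted regions fell at promoters in 3.73% of cases, in gene bodies in 37.5% and between genes in 58.8%, so promoters held 13.3 times the shifted share. In the replicates' own lists the promoter share was 60.1% ± 5.93 (SD, n = 2), with 55.9% in replicate 1 and 64.3% in replicate 2. With both lists held to 17150 regions by −log10 p these shares were 63.6% and 64.3%. In the looser overlap-thresholded set of 65382 regions 24.6% were at promoters. Of the 12734 distal regions, 13.4% lay within 1000 bp of the start of another annotated transcript, such as a non-coding RNA.

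Pan-neuronal and housekeeping genes mostly had promoter regions, and genes of blood, muscle, liver and the Hox clusters mostly did not. Of 28 pan-neuronal genes 27 had a promoter region (96.4% against 58.1% of other genes, odds ratio 19.5, adjusted p = 3.86e-05, Fisher's exact test), and of 26 housekeeping genes 25 did (96.2%, adjusted p = 7.16e-05). Both lists were also higher than lists matched on CpG content, where 68.0% and 80.2% were expected (adjusted p = 0.0012 and 0.0365, permutation test). None of the 39 Hox genes, which pattern the hindbrain and spinal cord, had a promoter region in the conservative set or in either replicate (adjusted p = 3.07e-14, Fisher's exact test), and 5 had one in the looser set. Among 26 neural progenitor genes 21 had one (odds ratio 3.03, adjusted p = 0.048, Fisher's exact test). That call was lost in each replicate's own list (18 members in replicate 1, 16 in replicate 2), with a promoter window of 500 bp, among the peaks above the median fold and against genes matched on CpG content (80.8% against 83.0% expected). Across the 18 lists, 3 were higher and 7 lower than other genes after adjustment, and 4 and 8 at an unadjusted p under 0.05.

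Within the pan-neuronal list the strongest promoters were those of Scg3, a protein of secretory granules, Syt1, the calcium sensor of synaptic vesicle release, and Nrxn1, a presynaptic adhesion molecule. The Scg3 region (chromosome 9, 75683314 to 75684984) had a fold enrichment of 16.6, and the regions of Syt1 (chromosome 10, 109010202 to 109011939) and Nrxn1 (chromosome 17, 90088049 to 90088796) had 16.5 and 16.2. The Nrxn1 region lay at an internal transcript start, 1004275 bp from the 5′ end of the gene. Among the other genes named here with a promoter fold, the regions of Pax5, Lhx2, Gad1, Pdgfra, Egfl7 and Fam111a also lay at a later start, from 3520 bp (Pdgfra) to 11124 bp (Lhx2) from the 5′ end. Rbfox3, which encodes the neuronal nuclear antigen NeuN, was the only member without a promoter region in the conservative set, and it had one in the looser set. Among housekeeping genes, Rab7 reached a fold of 14.02, Pgk1 13.9 and Rplp0 13.5, while Ubc had no promoter region except in the looser set. The neural progenitor genes were led by the inhibitor of differentiation Id4 (fold 10.7), the Hes family repressor gene Hes6 (8.66) and the intermediate filament gene Vim (8.20). Dll3, Msi1 and Neurog1 had no promoter region in either replicate or in the conservative set, and had one in the looser set.

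**Figure D1:**
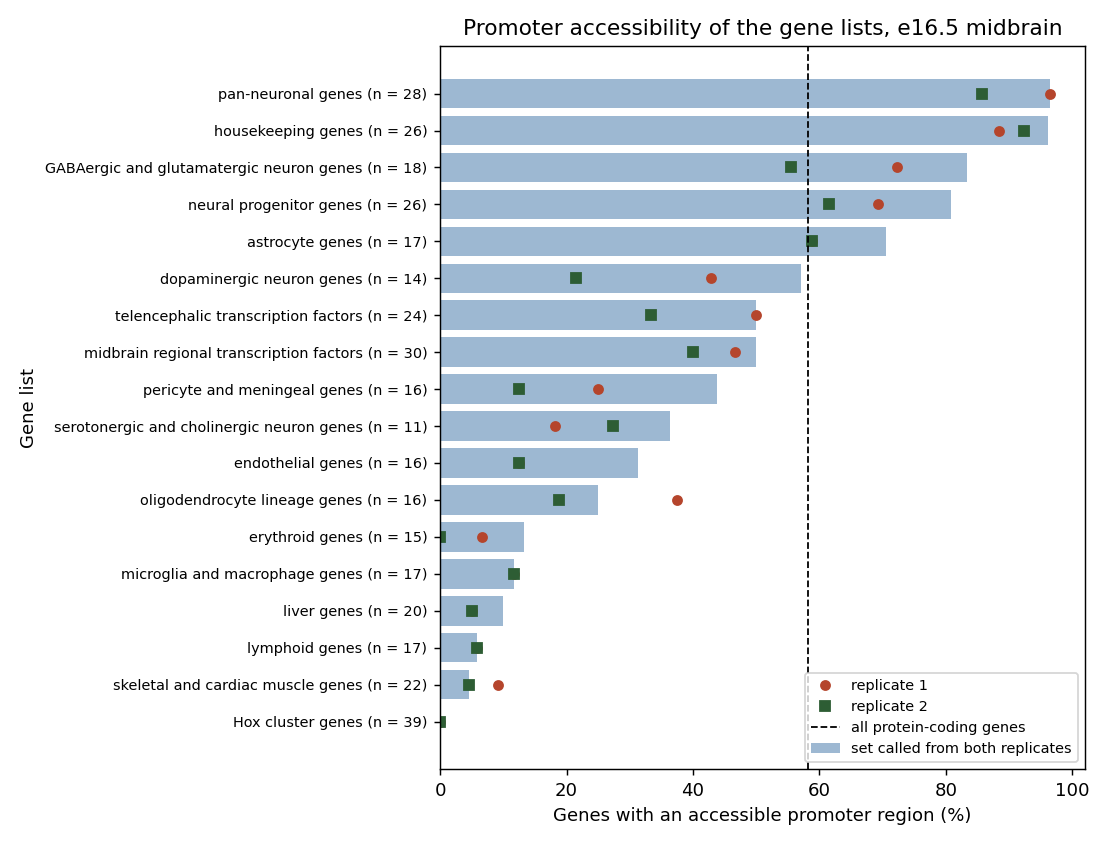
Percentage of the genes of each list (vertical axis, n genes per list) with an accessible promoter region. Bars show the conservative set, circles replicate 1, squares replicate 2 (covering the circle where both are equal) and the dashed line all protein-coding genes (58.1%); pan-neuronal genes reach 96.4% and Hox genes lie at 0.

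Transcription factors of the midbrain and of the telencephalon, the anterior part of the forebrain, had promoter regions in 15 of 30 and 12 of 24 cases. Neither list passed the threshold against other genes (adjusted p = 0.408 and 0.442, Fisher's exact test), but both were lower than lists matched on CpG content, where 84.9% and 72.6% were expected (adjusted p = 0.0012 and 0.0318, permutation test). The unadjusted p of the midbrain list, 0.0002, is the smallest that these permutations can give. In the looser set 28 of the midbrain and 22 of the telencephalic genes had a promoter region, and both lists were then higher than other genes (adjusted p = 0.00169 and 0.00829, Fisher's exact test). The strongest midbrain promoters were those of Pax5 (fold 9.19), which acts at the midbrain-hindbrain boundary, the sensory neuron factor gene Pou4f1 (8.16) and Irx2 (6.88). Barhl1, the floor plate factor gene Foxa2 and Foxb1 had none in either replicate or in the conservative set. The telencephalic list was led by Lhx2 (8.43), Arx (6.97) and Neurod1 (6.95). Dlx2, Emx1 and Emx2 had no promoter region in either replicate's list, although Dlx2 had one in the conservative set (fold 4.06).

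Neurotransmitter genes gave intermediate values. Of 18 GABAergic and glutamatergic genes 15 had a promoter region (adjusted p = 0.0522, Fisher's exact test), with folds of 9.61 at Calb1, a calcium-binding protein gene, 9.48 at Dlgap1 and 8.95 at the GABA receptor subunit gene Gabra1. Gad1, Npy and Slc17a6 had none in either replicate's list, while Gad1 (3.69) and Slc17a6 (2.72) had one in the conservative set. The list passed the threshold as higher in the looser set, with 17 members (adjusted p = 0.00989, Fisher's exact test), in the IDR list from splits of the pooled reads (88.9%, adjusted p = 0.0144) and with a promoter window of 2000 bp (88.9%, adjusted p = 0.025). Of 14 dopaminergic genes 8 had one (adjusted p = 1, Fisher's exact test), led by Nr4a2, a transcription factor of midbrain dopamine neurons (7.83), the dopamine receptor gene Drd2 (6.91) and Gch1 (6.75). Drd2 had its promoter region in the conservative set but in neither replicate's own list. Aldh1a1 and Ddc, which encodes the enzyme that makes dopamine from its precursor, had none in either replicate or in the conservative set. A distal region of the conservative set lay in an intron of Ddc (chromosome 11, 11867805 to 11868760, fold 8.70), 26 bp from the start of another annotated transcript, and each replicate's list also had 1 distal region nearest to Ddc. The list passed the threshold as lower than other genes in replicate 2 alone, with 3 members (adjusted p = 0.043, Fisher's exact test). Of 11 serotonergic and cholinergic genes 4 had a promoter region (adjusted p = 0.304, Fisher's exact test), with Isl1 (6.47), the serotonin transporter gene Slc6a4 (5.61) and Ache (5.38) highest. Chat, Fev and Htr1a had none in either replicate's list, and Htr1a had one in the conservative set (4.61). With replicate 1 alone this list passed the threshold as lower, with 2 members (adjusted p = 0.0272, Fisher's exact test).

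Of 17 astrocyte genes 12 had a promoter region (adjusted p = 0.404, Fisher's exact test), with Glul, glutamine synthetase, at 10.3, Nfia at 7.65 and Atp1b2 at 7.52. The Glul region also lay within 1000 bp of the start of Teddm2. Aldh1l1, Aldoc and the water channel gene Aqp4 had none in either replicate's list, while Aldh1l1 (5.61) and Aldoc (5.89) had one in the conservative set. Of 16 oligodendrocyte lineage genes 4 had one (adjusted p = 0.0194, Fisher's exact test), and these included Olig1 (7.58), Pdgfra (5.32) and Olig2 (4.85). Cspg4, Gpr17 and the myelin gene Mag did not. That call was lost in replicate 1, where 6 members had a promoter region (adjusted p = 0.287, Fisher's exact test), in the looser set, where 8 had one, in the IDR list from splits of the pooled reads (37.5%) and with a promoter window of 2000 bp.

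Markers of other cell types mostly lacked promoter regions, by Fisher's exact test against other genes. They were found for 2 of 17 microglia and macrophage genes (Irf8 and Hexb, adjusted p = 2.73e-04, exact test) and 2 of 15 erythroid genes (Gypa and Klf1, adjusted p = 0.00173). By the same exact test 1 of 22 skeletal and cardiac muscle genes (Myh7, adjusted p = 1.34e-06), 2 of 20 liver genes (Apoa1 and Apob, adjusted p = 3.86e-05) and 1 of 17 lymphoid genes (adjusted p = 3.86e-05) had one. The lymphoid exception was Foxp3, whose region also lay within 1000 bp of the start of Ppp1r3f. Against genes matched on CpG content the microglial, erythroid, liver and lymphoid lists no longer passed the threshold (adjusted p = 0.124, 0.937, 0.349 and 0.0808, permutation test), while the Hox (75.5% expected, adjusted p = 0.0012) and muscle lists (32.3% expected, adjusted p = 0.0063) did. The macrophage genes Aif1, C1qa and C1qb, the erythroid genes Alas2, Epor and Ermap, the muscle genes Acta1, Actc1 and Ckm, the liver genes Afp, Ahsg and Alb and the T and B cell genes Cd19, Cd3d and Cd3e had no promoter region in either replicate. Vascular lists did not pass the threshold, at 5 of 16 endothelial genes (adjusted p = 0.0605, Fisher's exact test) and 7 of 16 pericyte and meningeal genes (adjusted p = 0.401), but both were lower in each replicate's own list. The endothelial adjusted p was 0.00114 in replicate 1 and 0.00284 in replicate 2 (in the conservative set 0.00774 with 1 start per gene, 0.019 with a window of 500 bp and 0.0328 among peaks above the median fold), and that of the pericyte and meningeal list 0.034 and 0.00284, with 0.0328 among the conservative peaks above the median fold (Fisher's exact test). Neither vascular list passed the threshold against CpG-matched genes in the conservative set (50.1% and 50.8% expected, adjusted p = 0.129 and 0.757, permutation test). Erg (5.61), the vascular endothelial growth factor receptor gene Kdr (5.39) and Egfl7 (4.76) led the endothelial list, and Col1a1, Kcnj8 and Tbx18 the pericyte and meningeal list (5.28, 5.28 and 4.43). Cdh5, Cldn5, Emcn, Acta2, Col1a2 and Col3a1 had no promoter region in either replicate's list, and Cldn5 had one in the conservative set (3.95). The regions of Erg and of Klf1 were in the conservative set but in neither replicate's own list.

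Distal accessible regions were most numerous around pan-neuronal, progenitor and astrocyte genes. Pan-neuronal genes had 3.0 distal regions per gene against 1.27 in random lists matched on territory, neural progenitor genes 2.85 against 1.16 and astrocyte genes 2.65 against 1.03. These were the 3 lists past the threshold (permutation test, adjusted p = 0.0018, 0.0018 and 0.0084; the unadjusted p of the pan-neuronal and progenitor lists, 0.0002, is the smallest that 10000 random lists can give). In the same order their medians were 1.5, 2.0 and 2.0, and 19 of 28, 20 of 26 and 13 of 17 members had any distal region. Single members raised the means, with 15 regions at Myt1l and 12 each at Sox2 and Sox9. Matching in bins may not remove the effect of the longest territories, such as those of Celf4 (5103737 bp, 9 regions) and Sox9 (2553178 bp). Per replicate the means were 2.18 and 1.36 for pan-neuronal genes (0.919 and 0.597 expected), 1.89 and 1.19 for progenitor genes (0.837 and 0.545 expected) and 1.88 and 1.53 for astrocyte genes (0.742 and 0.481 expected). The progenitor call missed the threshold in replicate 2 (adjusted p = 0.054, permutation test), and the pan-neuronal call when all distal regions within 50000 bp of the start were counted (adjusted p = 0.0727). The GABAergic and glutamatergic (1.33 against 1.42 expected), dopaminergic (0.786 against 1.16) and serotonergic and cholinergic lists (0.909 against 1.05) did not pass it. After adjustment 0 of the 18 lists were lower. At an unadjusted p under 0.05 the Hox list alone was, with 0 distal regions against 0.133 per gene expected, and it passed the adjusted threshold when all regions within 50000 bp were counted and against lists not matched on territory. The oligodendrocyte list passed as higher in the looser set (adjusted p = 0.0018, permutation test) and in the IDR list from splits of the pooled reads (adjusted p = 0.0369), and the lymphoid list as lower in the looser set (adjusted p = 0.0342).

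Midbrain transcription factors had 2.37 distal regions per gene against 1.57 expected, which missed the threshold (p = 0.0366, adjusted p = 0.132, permutation test), and telencephalic factors had 1.33 against 1.31. Per replicate the midbrain means were 1.87 and 1.03 (1.13 and 0.728 expected). The midbrain list passed the threshold as higher in the looser set (adjusted p = 0.0081, permutation test) and against lists not matched on territory (adjusted p = 7.2e-04). The strongest near Pou4f1 lay between genes on chromosome 14 (104380715 to 104381783, fold 8.58), 86798 bp from the nearest start. The strongest near Irx2 was intergenic on chromosome 13 (72497459 to 72498094, fold 6.48) at 131145 bp. That of Pax5 lay in its own intron on chromosome 4 (44663566 to 44664814, fold 6.09), 319 bp from the start of another annotated transcript. Near Emx2, which had no promoter region in the conservative set, an intergenic region on chromosome 19 (59541587 to 59542688) had a fold of 12.5. The progenitor genes Id4 and Ascl1 had intergenic regions with folds of 10.2 (chromosome 13, 48227683 to 48228463) and 9.90 (chromosome 10, 87446895 to 87448238), against 10.7 and 4.04 at their promoters. In the astrocyte list Nfia had 7 distal regions (3 in replicate 1 and 5 in replicate 2), and Aqp4, with no promoter region, had 4 (4 and 1), of which the strongest lay in an intron of Chst9.

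**Figure D2:**
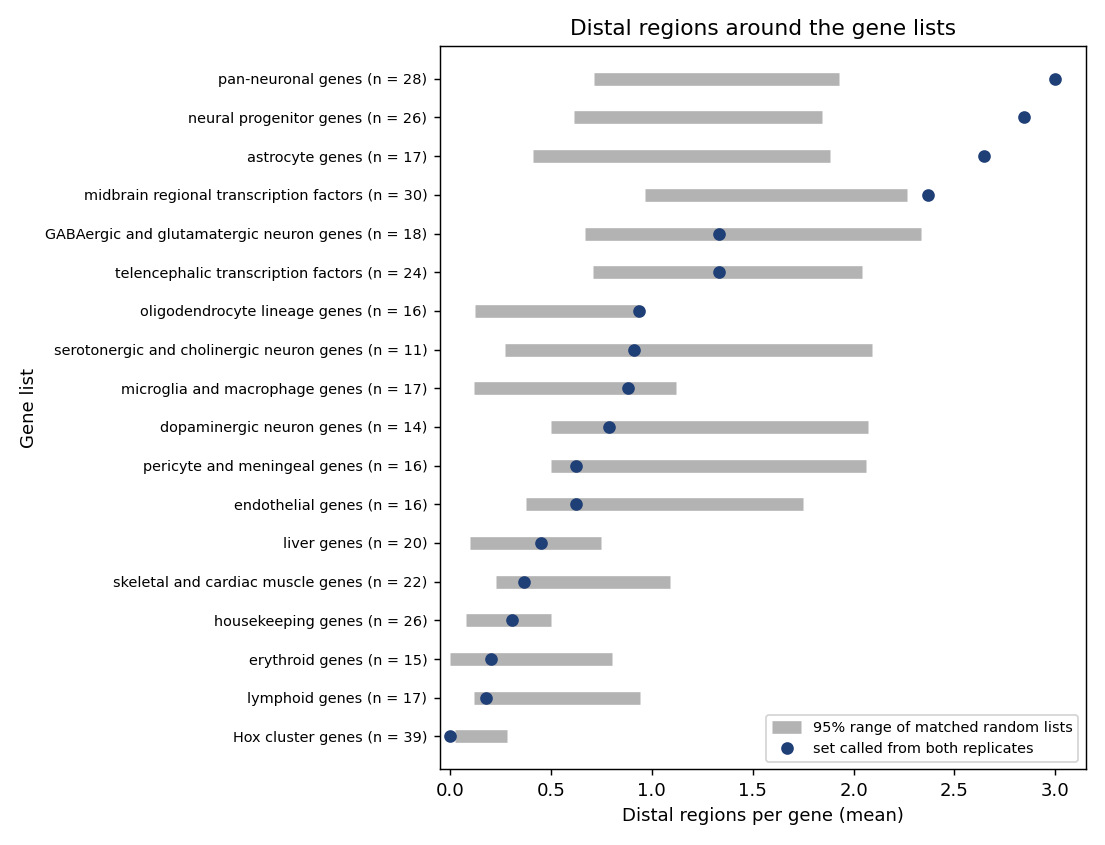
Mean number of distal regions per gene in the conservative set (horizontal axis) for each list (vertical axis, n genes per list). Points are the lists and grey bars the 95% range of 10000 random lists matched on territory; pan-neuronal (3.0), neural progenitor (2.85) and astrocyte genes (2.65) lie furthest beyond their ranges.

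In the conservative set the gene with the most distal regions was Rapgef5, an exchange factor for Ras-family GTPases, with 19. Dlg2, a postsynaptic scaffold gene, and Zfp608 had 16. The transcription factor genes Mef2c and Myt1l, the synaptic adhesion gene Nrxn3, Ubash3b and Usp29 had 15, and Gm11146 and Maml3 had 14. This order did not hold in the replicates' own lists. Among these 10 genes Myt1l, with 14 in each, had the highest count in both, level with Rapgef5 in replicate 1 (14), which had 7 in replicate 2. The counts in replicates 1 and 2 were 13 and 9 for Dlg2 and Usp29, 12 and 9 for Zfp608, Ubash3b and Gm11146, 10 and 10 for Mef2c, 13 and 6 for Nrxn3, and 10 and 8 for Maml3. Assignment was to the nearest start, and the strongest region of Rapgef5 lay in an intron of Ptprn2, 409203 bp from that start. The 15 regions of Myt1l, a neuronal factor in the pan-neuronal list, were found on chromosome 12. The strongest was intergenic (29290399 to 29291584, fold 15.6), 237184 bp from the nearest start, and above the promoter fold of 5.41. A second strong region lay in an intron of Myt1l (29872012 to 29872965, fold 12.1). Of the 12725 distal regions assigned to genes, 57.0% had their summit between genes, 39.1% in an intron, 2.38% in a coding exon and 1.56% in an untranslated region. The median distance to the nearest protein-coding start was 40780 bp.

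**Figure D3:**
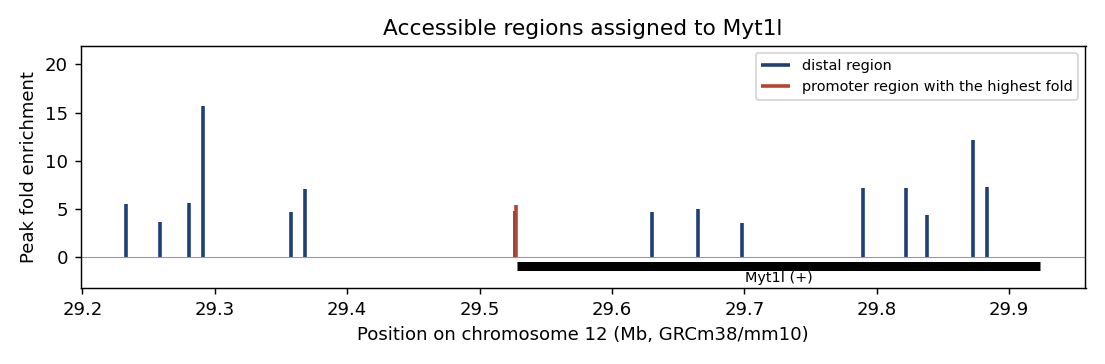
Map of the 15 distal regions assigned to Myt1l and its promoter region on chromosome 12 (horizontal axis, Mb, GRCm38/mm10; the black bar is the gene). The height of each line is the fold enrichment of the region; the highest is the intergenic region at 15.6.

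Promoters gave stronger peaks than distal regions. The median fold enrichment was 8.63 at the 12433 promoter regions (quartiles 6.08 and 11.5) and 5.55 at distal regions (4.58 and 7.04), a difference of 3.09. Within the replicates' own lists the difference was 2.54 ± 0.0941 (SD, n = 2). With the regions split into 10 equal groups by fold, promoters made up 34.1% of the lowest group, 24.4% of the next and 89.9% of the highest. Promoter regions were also wider, at a median of 1315 bp against 834.5 bp. The highest promoter folds were at the zinc finger gene Zfp960 (26.0), the start shared by the centrosomal gene Cep128 and Tshr (25.7) and Depdc1a (25.6). Lrriq1, Hltf, Fam111a, Iars, 6720489N17Rik and Ccdc89 followed with folds from 24.3 to 22.7.

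**Figure D4:**
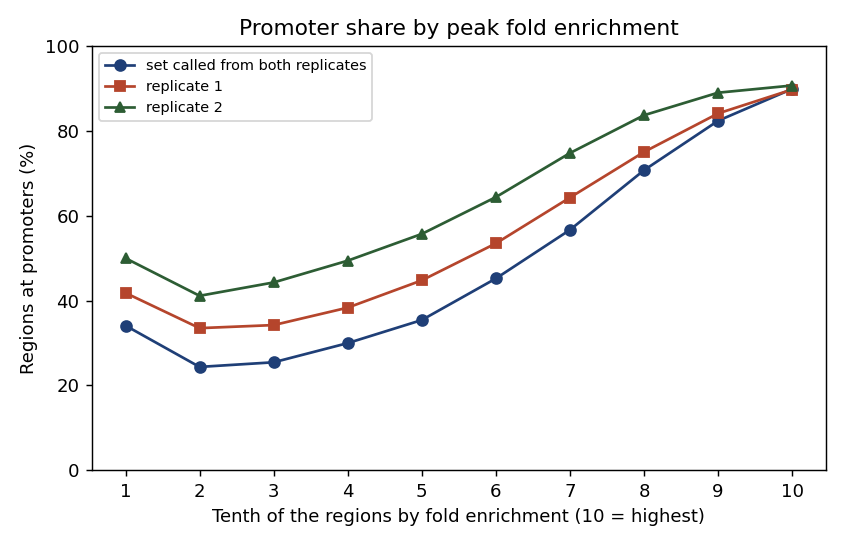
Percentage of regions at promoters (vertical axis) in each of 10 equal groups of regions by fold enrichment (horizontal axis, 10 is the highest). Lines show the conservative set and each replicate's list; in the conservative set the share goes from 34.1% in the lowest group to 89.9% in the highest.

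The 5 distal regions with the highest fold were narrow and intergenic. They lay on chromosome X (143482936 to 143483180, nearest gene Pak3, fold 53.8), chromosome 2 (69355469 to 69355735, Abcb11, 52.5), chromosome 5 (60042765 to 60043138, G6pd2 at 1765841 bp, 37.9), chromosome 2 (3964425 to 3964690, Frmd4a, 37.3) and chromosome 10 (96077546 to 96077952, Gm5426, 36.6). Their widths were 245, 267, 374, 266 and 407 bp. The regions nearest Abcb11, G6pd2 and Gm5426 shared 129, 336 and 352 bp with the mitochondrial genome, at identities of 100%, 97.6% and 97.4%.

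Regions found in 1 replicate only were mostly distal. In replicate 1, 19.2% (95% Wilson interval 18.2% to 20.3%) of the 5298 regions without an overlap in replicate 2 were promoters, against 68.3% (67.6% to 69.1%) of the 15635 shared regions. In replicate 2 the shares were 19.4% (17.5% to 21.6%) of 1414 and 68.3% (67.6% to 69.0%) of 15736. Their median fold was also lower, at 5.22 against 8.11 in replicate 1 and 5.72 against 8.46 in replicate 2. All but 457 of the 20933 regions of replicate 1 and all but 85 of the 17150 of replicate 2 overlapped a peak in the other replicate's looser, pseudoreplicated list. Of the list genes, 48 had a promoter region in a single replicate, 35 in replicate 1 and 13 in replicate 2. In alphabetical order the first were Apoa1 (replicate 2), Apob, Ascl1, Bcl11b, C1qc, Calb2, Celf4, Cnp, Col1a1 and Dcx (replicate 1).

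Distal summits were enriched for the binding sequences of the insulator protein CTCF and of RFX factors. A CTCF consensus was present at 10.8% of the 12734 distal summits and in 0.766% of flanks, a ratio of 14.1 (95% bootstrap interval 12.2 to 16.3, adjusted p = 9.53e-299, exact binomial test). The RFX consensus was rarer, at 1.32% against 0.0118%, for a ratio of 112.0 with a lower bound of 48.3 and no finite upper bound, since few flanks matched. Among sequences bound by neural factors, the E-box CAGCTG, of the type bound by ASCL1, had 19.3% against 9.29% (ratio 2.08, 1.97 to 2.20), the MEIS consensus 1.92% against 1.04% (1.85, 1.57 to 2.20) and the POU octamer 2.16% against 1.28% (1.68, 1.43 to 1.96). The E-box CAGATG, of the NEUROG and NEUROD type, had a ratio of 1.12 (1.07 to 1.18). The CTCF ratio was 13.8 in replicate 1 and 12.4 in replicate 2, and that of the CAGCTG E-box 2.18 and 2.15.

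Across the 22 consensus strings 14 were enriched, 4 depleted and 4 not past the threshold after adjustment. Against the flanks the general promoter sequences NRF1 (ratio 23.5), CRE (6.0), SP/KLF (4.51), YY1 (3.65), ETS (2.25) and NFY (2.25) were also enriched at distal summits. NRF1 matched 94 summits and YY1 42. The distal regions scanned include the 13.4% near the start of another annotated transcript, and no scan without them was run. Against shuffled strings of the same base composition in the same windows the ratios of NRF1, CRE and SP/KLF fell to 7.58, 1.35 and 1.19, and those of ETS and YY1 changed sides, to 0.586 (0.529 to 0.647) and 0.925 (0.665 to 1.22), while NFY had 2.02. Shuffling does not keep CG pairs, which the NRF1, CRE, SP/KLF, ETS and YY1 strings all hold. This control therefore cannot tell whether their enrichment against flanks comes from the strings themselves. The summits had 52.8% G and C against 44.8% in the upstream flanks. Depletion was found for FOX (ratio 0.567), GATA (0.657), OTX (0.813) and the homeodomain core TAATTA (0.868). SOX, AP-1, EBF and TEAD strings did not pass the threshold (ratios 1.00, 0.947, 0.884 and 1.04). Against shuffled strings SOX (1.94, 1.80 to 2.10), TEAD (1.60, 1.45 to 1.76) and AP-1 (1.15, 1.03 to 1.26) passed the threshold with ratios above 1. The OTX and homeodomain ratios changed sides to 1.13 and 1.15, FOX missed the threshold (0.938) and GATA stayed depleted (0.685). The ratios of CTCF (74.1), MEIS (4.59), POU (4.46) and CAGATG (2.02) were over 1.5 times those against flanks, and that of NFI fell to 2.94. Even in the flanks the shares of SOX (5.14%), TEAD (3.34%) and AP-1 (3.53%) were above the shuffled shares at summits (2.66%, 2.17% and 2.91%). The same held for OTX, the homeodomain core, CTCF, MEIS, POU and CAGATG. A ratio above 1 against shuffled strings therefore does not by itself show enrichment at summits. In the 50 bp window CRE had 10.4 and NRF1 38.7. NFI (10 summits, ratio 6.67) and MEF2 (1.38, interval 0.983 to 1.86) lost the threshold in each replicate, and MEF2 also against shuffled strings (1.24).

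**Figure D5:**
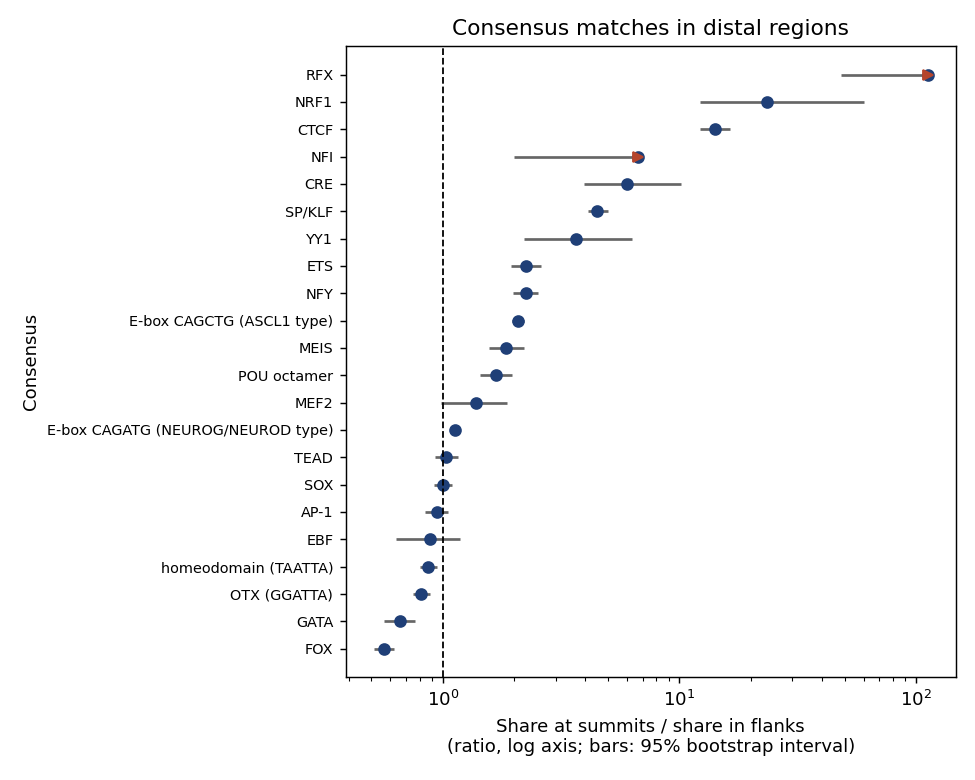
Ratio of the share of distal summits with a consensus match to the share of flanking windows (horizontal log axis) for 22 consensus strings (vertical axis). Points are ratios, bars 95% bootstrap intervals, red arrowheads mark intervals with no finite upper bound and the dashed line is equal shares; CTCF lies at 14.1 and FOX at 0.567.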

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

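All values here were described after they were seen. 1 result outside the main measurement stood out, since the comparisons above do not use it: 224 peaks of the true-replicate ranking passed the reproducibility threshold and are not in the conservative list. Of these, 74 lay on unplaced or unlocalised sequences and 150 on autosomes. The one with the highest −log10 p, 10594, lay on chromosome 1 (24611587 to 24616168) and matched the mitochondrial genome at 99.96% identity over at least 80% of its length. A pair of others in the leading 5 lay on chromosome 2, at 98666170 to 98667343 and at 98662444 to 98662923. Their removal was not explained in the sources used here.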

How the results depend on the processing

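Flanks at 5000 bp and the correlation over merged regions were chosen after seeing the data. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect could not be measured. Among the changes below, candidate causes were tested for the replicates' promoter shares and for the midbrain and telencephalic promoter calls. Those tests are given under the other observations, and no cause was tested for the rest. The overlap of replicate 1 with replicate 2 was 71.6% at 50% reciprocal overlap, 67.3% with pseudoreplicated lists and 82.0% at equal length, and that of replicate 2 with replicate 1 was 87.4%, 81.1% and 83.0%. In the replicates' own lists the promoter share ran from 55.9% to 64.3%, the gene body share from 14.5% to 18.5% and the intergenic share from 21.2% to 25.6%; in the overlap-thresholded set these were 24.6%, 37.9% and 37.5%. The promoter against distal difference in fold ran from 2.48 to 2.61 in the replicates and was 3.21 and 2.92 with windows of 500 and 2000 bp. With the 500 bp window the shared against single-replicate difference in promoter share was 50.2 points in replicate 1. The rank correlation was 0.939 over merged regions sharing 1 bp, 0.948 at 50% reciprocal overlap and 0.870 for pseudoreplicated peaks.

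In the overlap-thresholded set 6 lists were higher at promoters and 5 higher in distal regions, and 1 list was lower in distal regions, as with regions within 50000 bp (1) and lists not matched on territory (1). Directions changed for midbrain (93.3%) and telencephalic (91.7%) factors in that set, and for progenitor genes against CpG-matched lists (80.8%, the same share against a higher expectation). Shuffled strings reversed the homeodomain (1.15), OTX (1.13), AP-1 (1.15), ETS (0.586) and YY1 (0.925) ratios and gave 2 depleted strings, ETS and GATA, of which GATA alone was among the 4 depleted against flanks. They brought SOX (1.94) and TEAD (1.60) past the threshold with ratios above 1, but the flank shares of both were also above the shuffled shares. Shuffled strings do not keep CG pairs, so for strings that hold one this control cannot decide on enrichment. The 50 bp window reversed SOX (0.900), and MEF2 ran from 0.894 to 1.39 in the replicates, reversed in replicate 2. RFX gave no ratio in replicate 2, where no flank matched. Among single lists and strings, 376 values kept their direction and side of the threshold, 22 lost the threshold, 25 gained it and 10 reversed. Among the other values, such as shares and counts of calls, 58 stayed within the margin set for them and 28 moved beyond it.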

Other observations

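The gene families and the promoter sequence counts were chosen after the values were seen, as were the tests on mitochondrial matches over 100 bp, on the overlap-thresholded set and on median promoter fold; the other tests were written before their result was seen. Gene families differed in the share of genes with a promoter region, and were not matched on CpG content, which differed too. Among receptors of the nose, 4 of 1133 olfactory receptor genes (0.353%) and 1 of 330 vomeronasal receptor genes had a promoter region, and 1 of 53 keratin genes did. Of the clustered protocadherins, which give single neurons distinct surface identities, 4 of 56 had one. Ribosomal protein genes had one in 79 of 82 cases, proteasome genes in 37 of 40 and Zfp zinc finger genes in 334 of 394 (84.8%). Potassium channel genes had one in 57 of 94 cases with 1.29 distal regions per gene. Of 19 Sox genes 11 had a promoter region, with 3.37 distal regions per gene. Mean CpG counts within 500 bp of the start were 3.97 for olfactory and 3.85 for vomeronasal receptor genes, 27.5 for protocadherins and 23.4 for keratins, 61.2 for ribosomal protein, 55.2 for proteasome, 47.6 for Zfp, 49.2 for potassium channel and 71.1 for Sox genes. Fox genes had 72.4, with a promoter region in 22 of 44, so the order by CpG count is not the order by share. In the overlap-thresholded set 9 of the protocadherin, 16 of the Sox and 73 of the potassium channel genes had a promoter region.

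Promoter summits differed from distal ones in consensus counts and in base composition, with 65.6% G and C against 52.8%. At 12433 promoter summits the SP/KLF string was present in 52.2%, ETS in 18.2%, NFY in 15.3% and NRF1 in 5.40%, against 10.1%, 3.01%, 4.74% and 0.738% at distal summits. CTCF was present at 2.97% of promoter summits and the CAGCTG E-box at 11.6%. These shares are not matched on base composition.

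The 5 distal regions with the highest fold were narrow. A candidate explanation is mitochondrial reads placed on nuclear copies of mitochondrial DNA: 2 of the 5 matched the mitochondrial genome over 80% of their length at 90% identity, fewer than the 3 set beforehand, and with any match of at least 100 bp 6 of the 10 highest did, against 12 of all 12725 distal regions (Fisher's exact test, p = 3.3e-17). The regions nearest Pak3 and Frmd4a are the 2 of the 5 without such a match. Of the 5, 1 had a second copy on the assembled chromosomes over 80% of its length at 90% identity, which argues against long multi-copy repeats. Shorter, more diverged or unassembled copies could not be seen. Bases marked as repeats in the assembly made up 29.8% of the region nearest Pak3 and 8.27% of that nearest Frmd4a. In the regions nearest Abcb11, G6pd2 and Gm5426 they made up 54.3%, 5.08% and 14.25%. The CTCF consensus was in 0 of the 5, but only 10.8% of all distal summits held it, so this cannot decide on CTCF binding. What made the regions nearest Pak3 and Frmd4a stand out stays open, and no other biological explanation was tested.

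Midbrain and telencephalic transcription factor promoters were called in 50% of 54 cases, against 79.6% in lists matched on CpG content (95% range 70.4% to 88.9%). GC content bias is argued against as the whole cause, since lists matched on GC content gave a range of 59.3% to 81.5% and the observed share was 50%. In the overlap-thresholded set 92.6% of the 54 had a promoter region, within the matched range of 79.6% to 94.4%, and their median fold there was 4.26 against a matched range of 7.10 to 10.1. These 2 results are the same fact seen from different sides. The promoters may be open but weaker than those of CpG-matched genes, so that the reproducibility threshold removed them. Use in few cells of the tissue, or repression that leaves the promoter partly open, stay as untested hypotheses, since bulk peak lists hold no cell counts or histone marks.

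Replicate 2 had the higher promoter share, 64.3% against 55.9%, a difference of 8.37 points. A candidate explanation is that its list is shorter and ends higher in the same ranking. With both lists held to 17150 regions by −log10 p the shares were 64.3% and 63.6%, a difference of 0.641 points. What made the list of replicate 2 shorter, depth, signal over background or tissue, stays open, since read totals are unknown.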
